A study of Caenorhabditis elegans with 3 samples.

How the data were processed

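Each of 3 samples was a 2-colour microarray of Caenorhabditis elegans RNA, with a wild-type mixed reference in channel 1 and 1 preparation of early L4 hermaphrodites in channel 2, per the labels. The deposited values are log2 ratios of the 2 channels: at least 99.96% of the values per array, raised as powers of 2, gave whole thousandths (within 0.01 of a thousandth), so the logs were of ratios kept to 3 decimals, and very low ratios are coarse. The scanner, the dyes, the background correction, the normalization, the centring and the direction of the ratio are not given in the sources used here. The log2 columns deposited by the authors had medians of 0.054, -0.082 and -0.025 and SDs of 0.930, 0.813 and 0.777 for preparations 1, 2 and 3, so they were close to centred. Raw intensities were not used here, so neither background, saturation nor intensity-dependent dye bias could be examined, and no dye swap is recorded.

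Probes were named from the annotation of the platform, which is old, with symbols checked against the gene table of assembly WBcel235. Of 20000 probes, 15655 had 1 gene symbol, 198 had several and 4147 had no listed gene. Of the 15655, 15569 matched the gene table by gene number and 86 by symbol. Probes of several genes or of none were left out of the main test. Spots of 1 gene were averaged (467 of 15168 genes had more than 1 probe), and a gene was tested if at least 2 arrays had a value, which left 15159 genes; 15128 had values on all 3 arrays. No genome coordinates are printed because the build behind the array is not given in the sources used here.

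Each array was centred on its median, and the mean log2 ratio of each gene was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided, 2 residual and 7.59 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. The reference is no replicated group, so this test leaves out its own spread. Errors are SDs over the 3 arrays. Gene lists (24, of which 23 had at least 5 measured genes) were tested with camera at a preset inter-gene correlation of 0.01, against the other genes, on genes measured on all 3 arrays, with adjustment over the 23 lists. fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, and camera with an estimated correlation were run beside it. The lists covered sperm, oocyte and eggshell, meiosis, P granules, cell cycle, collagens, molting, hedgehog-related genes, vulva and gonad, heterochronic genes, muscle, neurons, intestine, early embryo, male-enriched genes, ribosome, respiratory chain, proteasome, heat shock, histones, detoxification, sex determination and vitellogenins.

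The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule took, among genes with a class name, values of 1 sign on all 3 arrays and adjusted p under 0.05, the 5 highest and 5 lowest mean ratios, the 2 most significant members in the direction of each list past the threshold, and all measured vitellogenins, 39 genes in all; every other gene named in the text, the closing section included, was chosen after its values were seen. Alternatives were the ratios as deposited, quantile normalization, genes measured on all 3 arrays, eBayes with trend and robust settings, each probe on its own, leaving out each preparation, ranks in camera, the estimated correlation, and, for the correlations between arrays, Spearman's; the test of every probe with unnamed ones included and fry were added after seeing the data. The pipeline was tested on simulated ratios for the 15159 genes of this comparison, with 200 changed genes. Each gene was drawn independently, with a variance drawn from the prior fitted to the measured variances. In all, 11% of genes changed 2-fold and 94% of genes changed 4-fold were recovered, and 5.41% of calls were false. With 200 changed genes the adjusted threshold is stricter than in the data, where 3444 genes passed, so these shares do not give the recovery in the data. A simulated list of 40 genes moved by 0.5 had a camera p of 1.9e-15 with the preset correlation and 0.0112 with an estimated one, and 0.5% of 200 unchanged lists had a camera p under 0.05 with the preset correlation. These lists held independent genes, so the share does not apply to lists whose genes move together. In the data the estimated correlation was 0.386 for the major sperm proteins.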

Results

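RNA of early L4 hermaphrodites of the nematode Caenorhabditis elegans was compared with a wild-type mixed reference on 2-colour DNA microarrays. L4 is the last larval stage before the adult molt, and hermaphrodites make sperm first and oocytes later. There was 1 group of 3 worm preparations, each hybridised on its own array with the reference in channel 1 and the early L4 RNA in channel 2. The labels do not say what was mixed to make the reference. Each array listed 20000 probes, of which 19905, 19841 and 19872 had a value for preparations 1, 2 and 3. The values were log2 ratios of the 2 channels, with no spot brightness, and there were only 3 arrays. Nothing in the labels states which channel is the numerator. The sign was read as early L4 over reference, which is likely because the descriptions name early L4 first, against the reference, and all arrays carry the same layout. "Higher" and "rose" below mean a positive ratio, hence more in early L4 under that reading.

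The 3 arrays correlated positively. Across 15128 genes measured on all of them, Pearson's r was 0.684 between preparations 1 and 2, 0.643 between 1 and 3, and 0.809 between 2 and 3. Genes are not independent replicates, so these values describe the arrays only. The reference and the channel layout are shared, with no dye swap recorded, so effects of the reference, the dyes and the probes can raise these correlations too. The median SD of a gene between the arrays was 0.36 on the log2 scale.

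The first comparison asked which genes differed between early L4 hermaphrodites and the reference. Of 15159 genes tested, 1917 were higher and 1527 lower at an adjusted p under 0.05 (limma, Benjamini-Hochberg), together 22.7% of the genes. A change of 2-fold or more was called for 1291 higher and 911 lower genes. Among genes with a gene-class name, irg-5 (F35E12.5), an infection response gene, was the highest, with a mean log2 ratio of 6.03 ± 0.44 (SD, n = 3; 65.5-fold). It was followed by 4 cuticle collagens: col-38 (F54C9.4) at 5.09 ± 0.90, bli-2 (F59E12.12) at 5.02 ± 0.68, bli-1 (C09G5.6) at 4.94 ± 1.61 and col-175 (C35B8.1) at 4.45 ± 0.80. bli-1 and bli-2 are named for the blistered adult cuticle of their mutants. At the other end stood hsp-12.6 (F38E11.2), a small heat shock protein, at -4.45 ± 0.07, and stha-3 (Y62H9A.5) at -4.39 ± 0.11. ule-3 (D1054.11), of a class named for expression in the uterine lumen, had -4.38 ± 0.62. The eggshell gene perm-2 (C44B12.1) had -4.18 ± 0.35, and acs-2 (F28F8.2), an acyl-CoA synthetase of fatty acid oxidation, had -4.15 ± 0.65. Adjusted p-values of these 10 genes lay between 6.82e-06 for irg-5 and 0.000166 for bli-1 (limma). The ratio against 0 leaves out the spread of the reference, which the labels name alike on all 3 arrays. Whether the preparations came from separate cultures is not stated, so p-values measure only the spread between these 3 arrays.

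**Figure D1:**
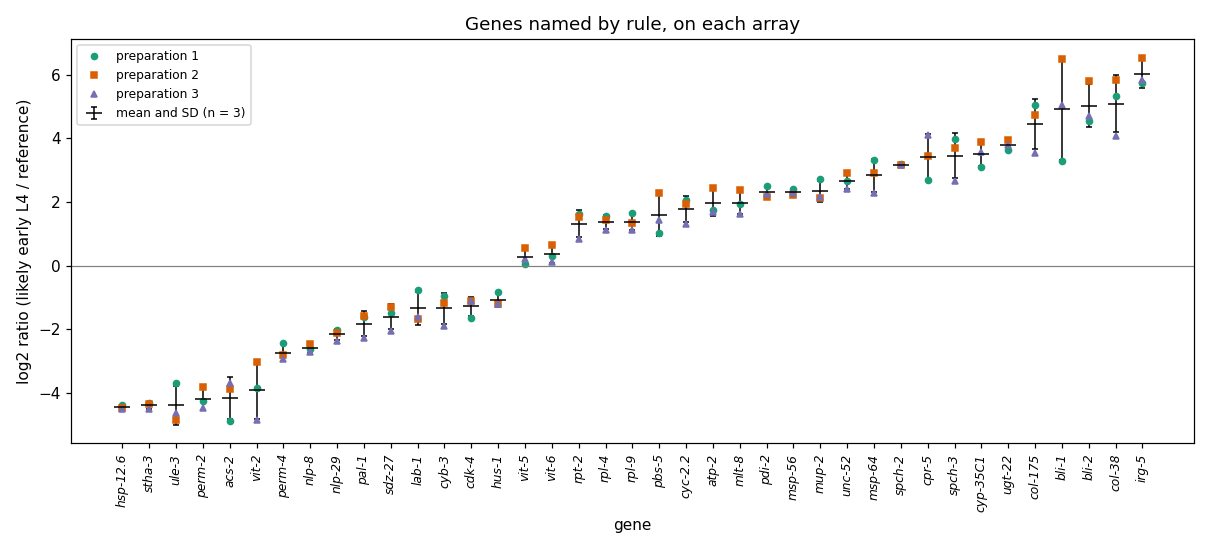
Log2 ratio (y axis, likely early L4 over reference) of the 39 genes named by rule (x axis, ordered by mean); symbols are the 3 preparations, and bars the mean ± SD (n = 3). The genes run from hsp-12.6 at -4.45 to irg-5 at 6.03, and bli-1 shows a wide spread between preparations, with an SD of 1.61.

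The second comparison asked which groups of genes moved, using lists fixed before the data were examined. Of 23 lists tested with camera, 10 were higher and 5 lower than the other genes at adjusted p under 0.05 with a preset inter-gene correlation of 0.01. With a correlation estimated from the 2 residual degrees of freedom, 0 lists passed in camera, 3 had an unadjusted p under 0.05, and fry called 14.

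Genes of the male gamete were higher. Of 30 genes for major sperm proteins, the motility and signalling proteins of nematode sperm, 28 rose and 2 did not pass, and the median log2 ratio was 1.78, a 3.43-fold difference (camera adjusted p = 1.01e-18; adjusted p = 0.248 with an estimated correlation). msp-64 (ZK1248.6) had 2.84 ± 0.51 and msp-56 (K07F5.3) 2.31 ± 0.11 (SD, n = 3). The count adjusted over the list alone was 29. These genes are near-identical copies whose probes can share RNA, so they are not separate measurements. Of 67 other sperm genes, 29 rose, 3 fell and 35 did not pass, with a median of 0.65 (camera adjusted p = 1e-08; adjusted p = 0.248 with an estimated correlation). In all, 34 rose and 3 fell adjusted over the list alone. The sperm chromatin genes spch-3 (T27A3.4) and spch-2 (C10G11.9) had 3.45 ± 0.71 and 3.18 ± 0.02. The 3 that fell, nspc-20, nspc-9 and nspc-13, belong to 1 family of small peptides and were named after their values were seen.

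Genes of the oocyte and eggshell were lower. Of 34 measured, 29 fell and 5 did not pass; the median log2 ratio was -1.63, a 3.09-fold difference, and lay between -1.49 and -1.77 on the 3 arrays (camera adjusted p = 1.01e-18; adjusted p = 0.217 with an estimated correlation). The count adjusted over the list alone was 30. The eggshell permeability barrier genes perm-2 and perm-4 (C44B12.5) had -4.18 ± 0.35 and -2.73 ± 0.26 (SD, n = 3). The yolk receptor rme-2 had -2.16 ± 0.15 and the oocyte maturation gene oma-2 had -2.34 ± 0.30; both were chosen after their values were seen. The 3 vitellogenin (yolk protein) genes with a probe of their own did not move together: vit-2 (C42D8.2) fell, with -3.90 ± 0.92 (limma adjusted p = 7.55e-05), while vit-5 (C04F6.1) had 0.28 ± 0.26 (adjusted p = 0.409) and vit-6 (K07H8.6) had 0.36 ± 0.26 (adjusted p = 0.291). These 3 genes therefore did not settle the direction of the ratio.

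Other germline lists moved less. Of 30 meiosis genes, 6 fell and 24 did not pass, with a median of -0.30 (camera adjusted p = 0.03; adjusted p = 0.335 with an estimated correlation). The same number, 6, fell adjusted over the list alone. lab-1 (C03D6.6), of meiotic chromosome cohesion, had -1.34 ± 0.51 and the DNA damage checkpoint gene hus-1 (H26D21.1) -1.08 ± 0.22 (SD, n = 3). Without preparation 2 the meiosis list no longer passed (camera adjusted p = 0.124). Of 45 cell cycle and DNA replication genes, 9 fell and 36 did not pass, with a median of -0.33 (camera adjusted p = 0.00116; adjusted p = 0.248 with an estimated correlation), and 8 fell adjusted over the list alone. The cyclin B gene cyb-3 (T06E6.2) had -1.34 ± 0.50 and the cyclin-dependent kinase cdk-4 (F18H3.5) -1.28 ± 0.30. The list of P granule and germline RNA regulators did not pass camera (median 0.13, adjusted p = 0.0764), with 9 genes up and 2 down; adjusted over the list alone, 9 were up and 3 down. The P granule helicase glh-1, at 2.51 ± 0.30, and the P granule gene pgl-1, at 1.38 ± 0.17, were among the 9 and were chosen after their values were seen.

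Cuticle and molting genes were higher than the other genes in camera with the preset correlation, with members in both directions. Of 153 cuticle collagens, 61 rose, 24 fell and 68 did not pass, with a median of 0.42 (camera adjusted p = 6.75e-05; adjusted p = 0.411 with an estimated correlation). These counts were 66 and 26 adjusted over the list alone. bli-2 and col-38 were the 2 most significant of those that rose, while col-36 had -4.14 ± 0.94 and col-158 -3.73 ± 0.09 (SD, n = 3; chosen after their values were seen). The median of the list was 0.88, 0.75 and 0.16 on the arrays of preparations 1, 2 and 3. Of 37 molting genes, 19 rose, 3 fell and 15 did not pass, with a median of 0.77 (camera adjusted p = 0.000135; adjusted p = 0.334 with an estimated correlation). Adjusted over the list alone, 21 rose and 3 fell. The protein disulphide isomerase pdi-2 (C07A12.4) had 2.3 ± 0.17 and mlt-8 (W08F4.6) 1.98 ± 0.37; the 3 that fell, named after their values were seen, were the cuticlin genes cut-1, cut-3 and cut-6. By fry, neither the collagens (adjusted p = 0.115) nor the molting genes (adjusted p = 0.0533) passed.

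Muscle and intestinal genes were higher and the neuronal list lower. Of 40 genes of body wall and pharyngeal muscle, 23 rose, 1 fell and 16 did not pass, with a median of 0.89 (camera adjusted p = 6.15e-11; adjusted p = 0.219 with an estimated correlation). unc-52 (ZC101.2), the perlecan of muscle attachment, had 2.66 ± 0.26 and mup-2 (T22E5.5), a troponin T, 2.34 ± 0.33 (SD, n = 3). The 1 that fell was the troponin C gene tnc-2. Of 46 intestinal genes, 26 rose, 3 fell and 17 did not pass, with a median of 0.95 (camera adjusted p = 5.17e-07; adjusted p = 0.264 with an estimated correlation). The glucuronosyltransferase gene ugt-22 (C08F11.8) had 3.79 ± 0.16 and the cathepsin B-like protease cpr-5 (W07B8.5) 3.41 ± 0.72. The metallothionein mtl-1, cpr-2 and the ferritin ftn-1 were the 3 that fell. Of 128 neuronal genes, 49 fell, 1 rose and 78 did not pass, with a median of -0.56 (camera adjusted p = 3.19e-09, and 0.248 with an estimated correlation). Most that fell were of the nlp and flp classes, 37 of 75, with a median of -0.71. Among the other neuronal genes 12 of 53 fell, with a median of -0.17. nlp-8 (D2005.2) had -2.60 ± 0.13. nlp-29 (B0213.4) had -2.16 ± 0.18 and encodes, as background, an antimicrobial peptide of the epidermis, so its class name does not make it neuronal. The 1 neuronal gene that rose was bas-1. Adjusted over the list alone, 26 muscle genes rose and 1 fell, 28 intestinal genes rose and 5 fell, and 56 neuronal genes fell and 2 rose.

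Lists of ribosomal, respiratory chain and proteasome genes were higher and early embryonic genes lower. Of 60 ribosomal protein genes, 23 rose and 37 did not pass, with a median of 0.64 (camera adjusted p = 1.39e-09; adjusted p = 0.264 with an estimated correlation). rpl-9 (R13A5.8) had 1.38 ± 0.27 and rpl-4 (B0041.4) 1.37 ± 0.22 (SD, n = 3). Of 36 genes of the mitochondrial respiratory chain, 20 rose and 16 did not pass, with a median of 0.74 (camera adjusted p = 4.74e-08; adjusted p = 0.248 with an estimated correlation). The ATP synthase subunit atp-2 (C34E10.6) had 1.96 ± 0.41 and the cytochrome c gene cyc-2.2 (ZC116.2) 1.77 ± 0.41. Of 31 proteasome subunits, 9 rose and 22 did not pass, with a median of 0.37 (camera adjusted p = 0.000135; adjusted p = 0.264 with an estimated correlation); pbs-5 (K05C4.1) had 1.59 ± 0.64 and rpt-2 (F29G9.5) 1.33 ± 0.43. Of 162 detoxification genes, 41 rose, 15 fell and 106 did not pass, with a median of 0.10 (camera adjusted p = 0.0267; adjusted p = 0.248 with an estimated correlation). ugt-22 led this list too, followed by the cytochrome P450 gene cyp-35C1 (C06B3.3) at 3.52 ± 0.39. The list mixed 3 families, which were also tested apart, among all gene classes, after the values were seen. The glucuronosyltransferases (ugt) passed, with 22 of 63 higher, 3 lower and a median of 0.35 (camera adjusted p = 0.000999; adjusted p = 0.673 with an estimated correlation). The cytochrome P450 genes (cyp) did not, with 9 higher and 7 lower of 67 and a median of 0.01 (adjusted p = 0.916), nor did the glutathione transferases (gst), with 10 higher and 5 lower of 32 and a median of 0.14 (adjusted p = 0.51). Of 61 early embryonic zygotic genes, 9 fell, 2 rose and 50 did not pass, with a median of -0.25 (camera adjusted p = 0.00696; adjusted p = 0.248 with an estimated correlation). The homeobox gene pal-1 (C38D4.6), whose RNA is also supplied by the mother, had -1.82 ± 0.39 and sdz-27 (R07H5.4) -1.60 ± 0.40; the 2 that rose were end-3 and sdz-3. Adjusted over the list alone, 32 ribosomal, 24 respiratory chain and 12 proteasome genes rose, 41 detoxification genes rose and 19 fell, and 7 embryonic genes fell and 1 rose.

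The remaining lists did not pass camera, and the single genes given for them were named after their values were seen. Of 70 hedgehog-related and patched-related genes, 13 rose and 8 fell (median 0.05, adjusted p = 0.361); adjusted over the list alone, 15 rose and 8 fell. Of 46 genes of vulva and somatic gonad development, 3 rose and 4 fell (median -0.01, adjusted p = 0.614), and 3 and 3 adjusted over the list alone. Among 13 heterochronic genes, which time larval fates, only the period-related lin-42 rose, with 1.33 ± 0.76 (SD, n = 3; list median 0.01, camera adjusted p = 0.77), as it did adjusted over the list alone. Of 26 heat shock genes, 9 rose and 5 fell (median 0.50, mean 0.11, adjusted p = 0.135), and 11 and 6 adjusted over the list alone. Of 61 histones, 11 rose and 3 fell (median 0.19, adjusted p = 0.0618), and the same numbers adjusted over the list alone. Among 19 sex determination and dosage compensation genes only fem-3 fell, with -1.06 ± 0.20 (list median -0.13, adjusted p = 0.277), as it did adjusted over the list alone. Of 19 male-enriched neuronal and tail genes 0 passed in limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (list median -0.13, camera adjusted p = 0.386).

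**Figure D2:**
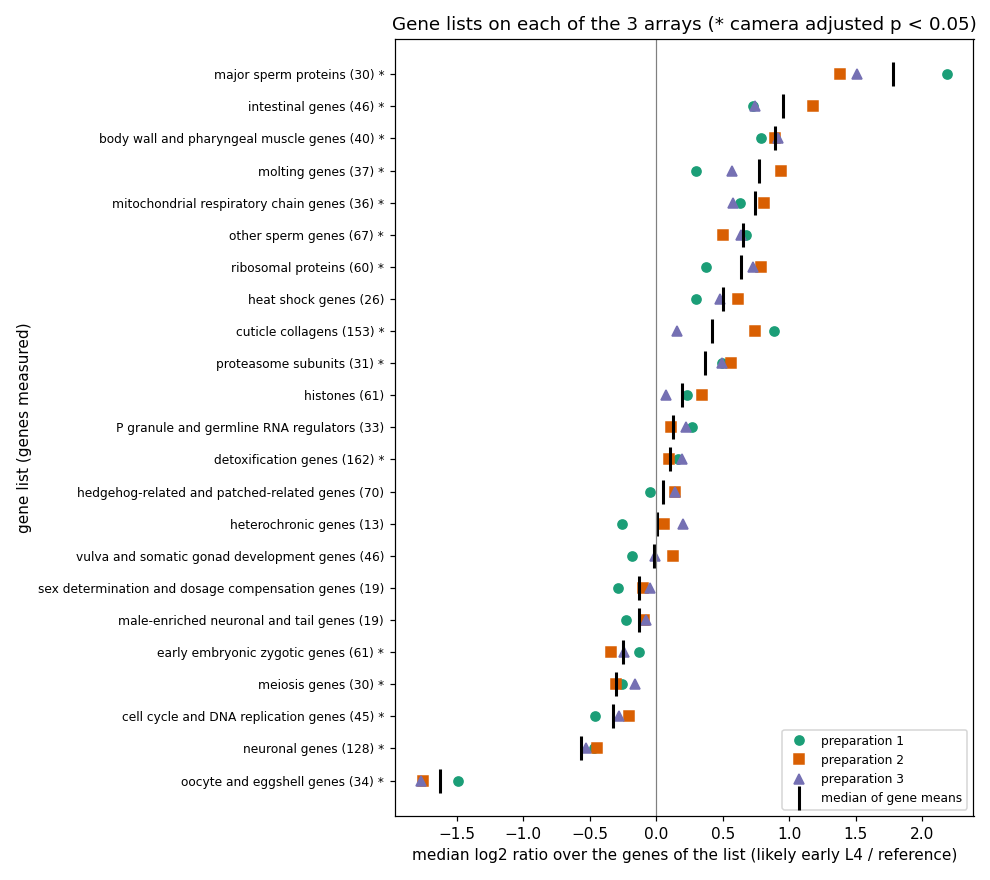
Median log2 ratio of each gene list (x axis, likely early L4 over reference) on each array; symbols are the 3 preparations, black marks the median of the gene means, and stars the lists past adjusted p 0.05 in camera. Major sperm proteins lie highest, with a median of 1.78, and oocyte and eggshell genes lowest, with -1.63.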

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

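The count of genes past the threshold stayed within 1.5 times its value of 3444 under every alternative run: 3580 with the ratios as deposited, 4022 after quantile normalization, 3137 with trend and robust settings, 3888 over every probe with unnamed ones included (added after seeing the data), and 2423 to 3931 with 1 preparation left out, the highest without preparation 1. The share of higher genes lay between 52.6% and 57.6%. Of the 3444, 3054 were also called without preparation 1, 2279 without 2 and 2459 without 3. All 39 named genes kept their direction and their side of the threshold in every alternative run on them. They had 1 sign on all 3 arrays, so leaving out 1 preparation could not turn their direction. Apart from the vitellogenins they were picked for extreme ratios or small p-values, so this says little about the other genes. The 23 lists kept direction and side with the ratios as deposited and after quantile normalization. Camera with an estimated correlation ended all list calls, from 15 to 0. That setting rests on 2 residual degrees of freedom, and its smallest adjusted p was 0.217 (0.00941 unadjusted, near the 0.0112 of a simulated list moved by 0.5). The estimate was 0.386 for the major sperm proteins. For oocyte and eggshell genes (0.0017) and muscle genes (0.0071) it lay under the preset 0.01. For the oocyte and eggshell genes and the muscle genes the loss of the call thus came from the few degrees of freedom, not from a higher correlation. Other called lists had estimates above the preset, such as the collagens (0.183), ribosomal proteins (0.152), molting genes (0.146) and intestinal genes (0.130). For lists with such estimates the higher correlation can have added to the loss, and the p-values with the preset correlation can overstate the evidence. Ranks added the histones (adjusted p = 0.029), and fry called the P granule list (0.0305) but not the collagens or the molting genes. The number of lists past the threshold was 14 to 15 with 1 preparation left out. The median correlation between arrays fell from 0.684 by Pearson to 0.573 by Spearman; the cause was not tested. No paired analysis was possible because there was 1 group. With the sign of 1 array turned, the highest number of genes past the threshold was 0, against 3444 with the real signs. Of the 4 sign patterns 1, the real one, gave as many, and 4 patterns are too few for a share under 0.05. The positive correlations between the arrays, whatever their cause, already made such a drop likely, so it adds no separate evidence. Spot brightness was not used here, so what signal over background limits could not be seen.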

Other observations

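The gene classes below, the oocyte test of direction, and the choice of the starvation, pathogen response and chemoreceptor lists came after results had been seen. All single genes named in this part, except those of the rule, were also picked after their values were seen. Camera was run on 149 gene classes with at least 10 measured genes; it called 30 with the preset correlation, many of them parts of the fixed lists, and 0 with an estimated one, where 7 had an unadjusted p under 0.05. Of the 96 classes with no gene in a fixed list, 16 were called, 6 higher and 10 lower, and with an estimated correlation 0 were, with 4 at an unadjusted p under 0.05. Neither 7 of 149 nor 4 of 96 is more than the share of 0.05 expected without any difference. That setting has little power, however. The oocyte and eggshell list, with 29 of 34 genes lower, had an unadjusted p of only 0.00941 in camera with an estimated correlation. These shares therefore cannot show that no class differed. Of 13 abu genes, first described as activated in blocked unfolded protein response, 10 were higher, with a median log2 ratio of 1.27 (adjusted p = 2.86e-06; adjusted p = 0.673 with an estimated correlation). Of 12 acyl-CoA dehydrogenase genes (acdh), 8 were higher, with a median of 1.07 (adjusted p = 5.29e-05; 0.673 estimated), led by acdh-1 at 3.62 ± 0.64 (SD, n = 3). Of 17 vacuolar ATPase genes (vha), of which vha-6 is also in the intestinal list, 8 were higher, with a median of 0.59 (adjusted p = 0.00206; 0.852 estimated). Of 46 transthyretin-related genes (ttr), 17 were lower and 3 higher, with a median of -0.42 (adjusted p = 0.000166; 0.673 estimated), and of 28 chitinase-like genes (chil), 8 were lower, with a median of -0.47 (adjusted p = 0.000318; 0.673 estimated). Of 22 insulin-related genes (ins), 5 were lower, with a median of -0.37 (adjusted p = 0.0333; 0.728 estimated).

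Among the 26 heat shock genes, 9 of which were higher and 5 lower, the highest were hsp-3 and hsp-4, the BiP chaperones of the endoplasmic reticulum, with log2 ratios of 2.32 ± 0.15 and 1.89 ± 0.20 (SD, n = 3). The lowest were hsp-12.6, hsp-12.3 and sip-1, with -4.45 ± 0.07, -2.63 ± 0.66 and -2.52 ± 0.66. Small heat shock genes were found on both sides, since hsp-16.1 was higher, with a mean of 1.55. Among the hedgehog-related genes, wrt-6 had 2.98 ± 0.59 and grl-7 2.88 ± 0.89, against -2.17 ± 0.49 for grl-3 and -2.07 ± 0.63 for grl-20. All of these passed the limma test.

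The direction of the ratio was tested with yolk genes, chosen before the data were examined, and oocyte genes, chosen after. If the ratio were reference over early L4, oocyte and eggshell genes would be higher in early L4 than in the reference; their median was -1.63, with 29 of 34 lower, which argues against it under the background knowledge that oocytes form after this stage. The yolk test, the only one planned, came out on the other side: the median of vit-2, vit-5 and vit-6 was 0.28, and a median above 0 had been set as the outcome of a ratio of reference over early L4. It is read as undecided because the 3 genes part: vit-2 stood at -3.90 ± 0.92, while vit-5 and vit-6 did not pass the test. The case against a reversed ratio thus rests on the oocyte test, which was written after its result was seen. Why vit-2 parts from vit-5 and vit-6 was not tested; a wrong assignment of 1 of these probes stays open, since each gene had a single probe.

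Cuticle collagens varied between preparations more than other genes. Their median SD of 0.626 over 153 genes compares with 0.402 for the median of 10000 random lists matched on the size of the ratio. It lay at percentile 100 of those lists, which argues against spread that merely grows with the ratio. The collagens moved together (estimated correlation 0.183) and random genes need not, so that percentile can overstate the evidence. The near-identical major sperm proteins lay at percentile 39.2 of their own matched lists, which does not bear on probes shared between collagens, since shared probes make copies move together without setting the size of each SD; that explanation stays open. A candidate explanation is that the preparations stood at slightly different points of the molting cycle; the median collagen deviated by 0.22, 0.16 and -0.36 from its mean on the arrays of preparations 1, 2 and 3, and the molting genes lay at percentile 92.8. The molting genes did not follow the collagens: their medians on these arrays were 0.30, 0.94 and 0.57, lowest on preparation 1, where the collagens were highest, so this explanation stays undecided. Preparation and array are the same unit here, so a hybridisation effect on collagen probes alone stays open.

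Within the neuronal list, 37 of 75 genes of the nlp and flp classes fell, with a median of -0.71, against 12 of 53 and a median of -0.17 for the other neuronal genes. The nlp class is named for neuropeptides but holds members such as nlp-29, an antimicrobial peptide of the epidermis. Taken apart, 27 of 53 nlp genes fell, with a median of -0.71, and 10 of 22 flp genes, with a median of -0.72. The flp class passed on its own (camera adjusted p = 6.18e-05 over the 149 classes, and 0.673 with an estimated correlation), so such nlp members do not account for the whole fall. In which cells these genes fell was not measured. The difference between the nlp and flp genes and the other neuronal genes was not tested. A smaller neuronal share of the RNA may contribute, but it needs both parts to fall alike, and on the array where a part was highest its median was -0.15, short of the -0.28 or less set as the bound, so the test did not decide. A bias of dim spots would be expected to lower chemoreceptor genes too, and 1084 of these had a median of 0.0281. Their medians were 0.18, -0.10 and -0.05 on the arrays of preparations 1, 2 and 3, so the sign differed between arrays. Spot brightness was not used here, so that chemoreceptors are dim was not measured and this bias stays open.

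One hypothesis was that the reference held more RNA of starved or dauer animals, since acs-2 and hsp-12.6 were among the lowest genes. The other 30 starvation and dauer genes, of which 5 are also in another list, had a median of -0.49, with 10 lower and 3 higher (camera adjusted p = 0.00857 over 3 lists; adjusted p = 0.922 with an estimated correlation). Adjusted over the list alone, 13 were lower and 4 higher. scl-2 had -2.67 ± 0.27 and fil-1 -2.46 ± 0.93, but the gluconeogenic pck-1 had 2.89 ± 1.28 (SD, n = 3). The median just missed the -0.5 set beforehand, so the hypothesis is left undecided. A second hypothesis was that pathogen response genes were higher as a group, after irg-5, irg-8 (3.77 ± 0.11) and irg-7 (3.03 ± 0.66). The other 32, of which 7 are in another list, went both ways, 9 higher and 10 lower, with a median of 0.0608 (camera adjusted p = 0.831), and adjusted over the list alone 11 were higher and 12 lower. irg-4 had 2.49 ± 0.59 and dod-3 -2.85 ± 0.33. The pals class, known from the response to intracellular pathogens, went the other way, with 7 of 24 genes lower, 17 not past the test and a median of -0.56 (camera adjusted p = 0.00014 over the 149 classes; 0.673 estimated).

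No chromosome of assembly WBcel235 was called different from the others. In camera 0 of the 6 chromosomes passed, with a smallest unadjusted p of 0.411 for chromosome IV. The preset correlation weighs heavily on sets of 1941 to 3893 genes, so small shifts would not be called. The mean log2 ratio lay between 0.010 for chromosome X and 0.075 for chromosome IV. The mean log2 ratio of X-linked genes was 0.02 below that of autosomal genes (difference -0.0209). Without the 239 genes of the germline lists the difference was -0.0147. Chromosome X was not called different to begin with (camera unadjusted p = 0.917), so whether those lists account for a small X shift could not be told.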
